A study of Mus musculus with 6 samples.

How the data were processed

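RNA sequencing on the BGISEQ-500 platform had been done on total RNA of 6 mouse libraries, 2 of MEFs, 2 of CiSCs and 2 of MSCs. The authors deposited 1 file per library with expected counts per gene (estimated read counts that need not be whole) under Entrez Gene identifiers. Per the labels, HISAT, an alignment program, and the mouse build mm9 had been used, with no version or settings given. The counting program, the annotation and any filter were not stated, and neither was the strand of the libraries. Between 42.0% and 43.8% of the values in a library were not whole (tolerance 1e-09), and library totals differed. Expected counts would give this, but some normalised values would as well, so these checks cannot exclude normalised values.

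Totals were 19809100 and 19301800 counts for the MEF libraries, 19294700 and 19658800 for the CiSC libraries, and 20418600 and 19971200 for the MSC libraries. A count of 0 in both libraries of a group allows up to 3 reads over the group, or 0.0769 CPM in MEFs, 0.0708 CPM in CiSCs and 0.0806 CPM in MSCs. With 1 to 3 reads in a group, a ratio is given with its exact binomial 95% interval where it is printed. Reads carried no molecular identifiers, so these limits cover counting error only. Of 20007 gene identifiers, 18891 matched a gene symbol in a RefSeq table of the mouse assembly GRCm38, which is not the build of the alignment, so no coordinates are given. The 1116 others, of which 972 had a format of the submitters' own (674 of these tested), were counted where they passed the filter but not named.

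Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the default filter on low counts (filterByExpr), libraries were scaled with the trimmed mean of M values (TMM), and a quasi-likelihood model with 1 mean per group was fitted to all 6 libraries, with 3 residual degrees of freedom. Levels in CPM used the scaled library sizes. Log2 CPM values used a prior count of 2. The comparisons were CiSCs against MEFs, MSCs against MEFs and CiSCs against MSCs, each with two-sided F tests and a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The standard error of a log2 fold change was its size divided by the root of its F value. Of 38 gene lists written before the data were examined, 36 had at least 3 tested members and were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Distances and correlations between libraries were computed over log2 CPM of the tested genes.

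Genes to be named were chosen by a rule written before the data were examined. It took, for each comparison, the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean of at least 10 CPM in the higher group and groups that did not overlap, passing over unnamed gene models. It took up to 4 members with the smallest adjusted p from each list described, or the 2 with the highest mean where none passed, and a fixed set of Sertoli cell, fibroblast and sex chromosome genes. Of that set Xist was not analysed here, and the same holds for H19, Meg3 and 5 other list members. Some genes that the rule chose are not reported here. The procedure was tested on simulated data, with steps added to genes of the real count level and spread. It recovered 84.8% of 4-fold, 20.9% of 2-fold and 1.49% of 1.5-fold changes for CiSCs against MEFs, with 9 false calls among 80. For CiSCs against MSCs, 12 of 100 calls were false, and for MSCs against MEFs 5 of 77.

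The alternatives were leaving out each library in turn, the replicate number as a block, only the 2 groups compared in the fit, an adjusted p under 0.01, a test against a fold of 1.5, no filter, a filter of at least 5 CPM in at least 2 libraries, only genes above 0 in all libraries, median-ratio size factors, DESeq2 1.42.0 with its Wald test, a separate MEF library as the control of each change, and the 1000 most variable genes or Pearson's correlation for similarity. Counts not rounded, only identifiers matched to a symbol, and a set without leukocyte-like genes were added after the data had been seen. No library was left out of the values reported.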

Results

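Gene expression was measured by RNA sequencing on the BGISEQ-500 platform in 6 libraries from mice of the KM strain. The libraries fell into 3 groups of 2. MEFs were embryonic fibroblasts prepared from embryos that the labels put at 13.5 days post coitum, although the growth protocol also allows an earlier day. CiSCs were passaged MEFs that had been exposed to small-molecule compounds, which the labels do not name, to induce a Sertoli-like state. MSCs were Sertoli cells, the somatic nurse cells of the seminiferous tubule, prepared from testes at postnatal day 60 and plated in culture. The stated purpose of the series was to compare the genome-wide expression profile of the induced cells with that of Sertoli cells. Each library held between 19294700 and 20418600 expected counts over all genes, so that 1 read corresponded to 0.0468 to 0.0543 CPM (counts scaled to library size). Of 20007 gene identifiers, 15272 had enough counts to be tested. Levels are CPM as mean ± SD over the 2 libraries of a group, and log2 fold changes are given ± their standard error. A fold against a group with 0 reads is a lower bound, taken against 3 reads over the group, and such bounds and intervals cover counting error only. Where no count adjusted over the list alone is given beside a gene list, it equalled the count over all tested genes. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Because the labels do not say whether the 2 libraries of a group came from separate cultures or animals, these p-values measure the spread between these libraries only, which may be technical.

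The first question was how close the whole profile of CiSCs lay to those of the other groups. Across the 15272 tested genes, the mean Euclidean distance between log2 CPM profiles was 219 for CiSCs and MEFs (4 pairs of libraries, range 207 to 229.5). It was 231 for CiSCs and MSCs (range 228 to 233) and 221 for MSCs and MEFs (range 212 to 228). Replicate libraries lay much closer together, at 86.9 in MEFs, 55.6 in CiSCs and 53.9 in MSCs. The ratio of the CiSC-MSC distance to the CiSC-MEF distance was 1.06. Single libraries of each group gave ratios from 0.994 to 1.11, so by distance over all tested genes CiSCs were not distinguishably nearer to one group than to the other. Without leukocyte-like genes, a set defined below and taken out after the data had been seen, the ratio was 1.29. The choice of that set itself raises the ratio. Mean Spearman correlations across genes, which are not independent replicates, were 0.848 for CiSCs with MEFs and 0.843 for CiSCs with MSCs. Their difference was smaller than its spread between single libraries (SD 0.0211). Pearson's correlation was higher with MEFs, at 0.818 against 0.792 with MSCs. Each pair of a CiSC and a MEF library (0.800 to 0.837) exceeded each pair of a CiSC and an MSC library (0.788 to 0.797), so the measures did not agree. The first principal component (50.8% of the variance) separated CiSCs from MSCs with MEFs between them, and the second (42.9%) separated MEFs from the other groups.

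CiSCs were compared with MEFs to describe how the induced cells differed from the cells they came from. None of the 3 groups is described as passaged MEFs without the compounds. Effects of passaging and culture can therefore not be told apart from those of the compounds. In CiSCs a part of the Sertoli cell markers and most tested retinoic acid response genes, HOX genes and imprinted growth genes were higher, and most leukocyte and inflammatory genes were lower, the leukocyte markers by a median log2 fold change of -8.81. As lists, the retinoic acid, HOX, imprinted, leukocyte and inflammatory genes passed by camera, and none of them did with an estimated inter-gene correlation (adjusted p from 0.285 to 0.499). That setting also leaves camera only the 3 residual degrees of freedom of the fit, which by itself raises p. Clu (Entrez Gene 12759), which encodes the secreted chaperone clusterin, stood at 5.77 ± 0.147 CPM in MEFs and 4375 ± 504 CPM in CiSCs, a log2 fold change of 9.57 ± 0.34 (adjusted p = 1.49e-05, edgeR). Stra6, the receptor for cellular retinol uptake, rose from 0.410 ± 0.00790 to 490.0 ± 23.7 CPM, and Igf2, an imprinted fetal growth factor, from 34.6 ± 1.72 to 1740.5 ± 134 CPM. In the opposite direction, the myeloid integrin subunit Itgam fell from 637 ± 122 to 2.00 ± 0.473 CPM.

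The Sertoli cell marker list was mixed. Of its 30 tested members, 9 were higher in CiSCs, 4 were lower and 17 did not pass. The list's median log2 fold change was 0.79, or 0.72 with genes at 0 in a group set to their bound, and the list did not pass against other genes (camera adjusted p = 0.132). It passed without the first CiSC library (adjusted p = 0.0305), with only CiSCs and MEFs in the fit (0.0353), with a stricter filter on low counts (0.0389) and with genes above 0 in all libraries (0.0343). Besides Clu, the retinoic acid-degrading enzyme Cyp26b1 rose from 6.45 ± 1.25 to 1134 ± 26.2 CPM and the gonadal transcription factor Wt1 from 1.36 ± 0.0624 to 21.7 ± 0.901 CPM (log2 fold change 3.99 ± 0.20, adjusted p = 3.12e-05, edgeR). Cyp26b1 is also a member of the retinoic acid response list, so its rise counts in both lists. The keratin gene Krt18 rose from 1.26 ± 0.205 to 12.8 ± 3.68 CPM. Cldn11, a tight-junction claudin of the blood-testis barrier, passed the test at low levels, 0.0765 ± 0.0348 CPM in MEFs and 1.09 ± 0.119 CPM in CiSCs, with a counting ratio of 14.1 (95% interval 4.54 to 71.0). The transferrin gene Trf fell from 112 ± 16.5 to 2.998 ± 0.0587 CPM, in the same libraries in which leukocyte markers such as Itgam fell. Several central regulators did not pass. Sox9, a transcription factor gene of Sertoli cell differentiation, stood at 13.8 ± 2.51 and 15.8 ± 1.62 CPM (log2 fold change 0.19 ± 0.20, adjusted p = 0.475, edgeR). Inhbb, an inhibin and activin subunit, was at 77.4 ± 4.43 and 68.4 ± 9.16 CPM, and the germ cell niche factor Gdnf at 1.33 ± 0.119 and 1.93 ± 0.240 CPM. Gata4, Amh and Dmrt1 were near the detection limit in both groups (0.154 ± 0.00296 and 0.0945 ± 0.00131 CPM for Gata4, 2 and 10 reads for Amh, 0 and 3 for Dmrt1). The receptor gene Fshr had 0 reads in both. For these 4 genes a difference was not detectable at this depth.

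**Figure D1:**
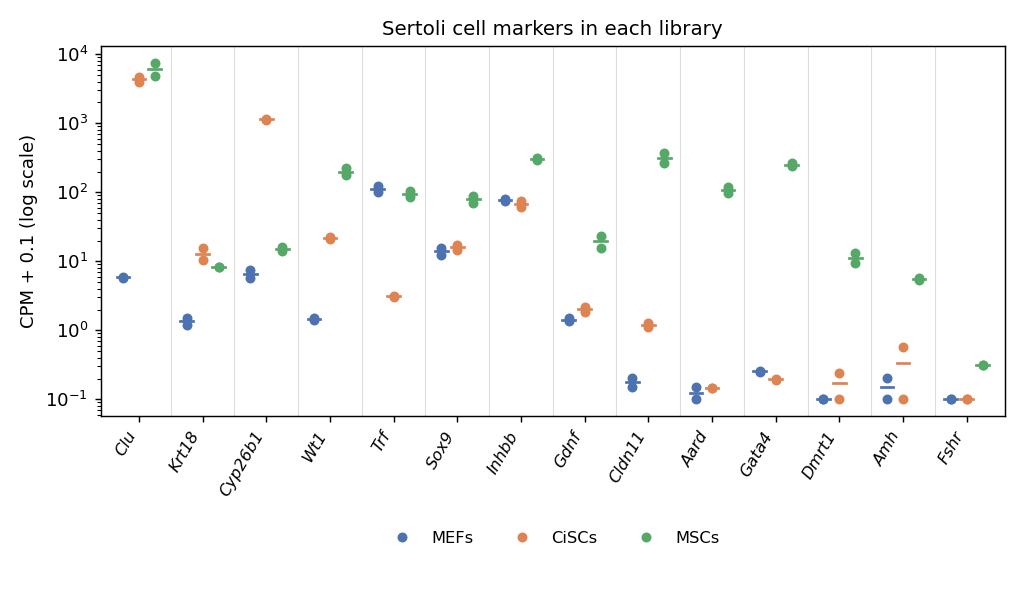
Levels of 14 Sertoli cell markers in each library, as CPM + 0.1 on a log axis. Points are single libraries and bars the mean of 2. Clu had a mean of 4375 CPM in CiSCs and 6188 CPM in MSCs, whereas Gata4 was at 0.0945 CPM in CiSCs and 252 CPM in MSCs.

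Junction genes of the blood-testis barrier, a list of 19 tested genes, included 7 that rose and 2 that fell, and the list as a whole did not pass (camera adjusted p = 0.0716), although it did with only CiSCs and MEFs in the fit (adjusted p = 0.0462), with a stricter filter (0.0170), with genes above 0 in all libraries (0.0157) and without leukocyte-like genes, a set defined below and taken out after the data had been seen (0.0322). Jam2 rose from 7.76 ± 3.04 to 134 ± 6.62 CPM, F11r from 22.9 ± 0.223 to 120.0 ± 4.13 CPM and Gja1, which encodes connexin 43, from 49.8 ± 17.4 to 207 ± 7.80 CPM. Among early gonad regulators, 5 of 10 rose, among them Gata6 (1.43 ± 0.117 to 39.2 ± 0.542 CPM), and 3 fell (camera adjusted p = 0.266). Of the 10 tested Leydig cell and steroidogenic genes, 0 passed by edgeR and 0 by DESeq2, with 2 at an unadjusted p under 0.05. The list's median was -0.10, or 0.00 with genes at 0 in a group set to their bound, while camera placed it on the upper side (adjusted p = 0.852). Cyp11a1, the cholesterol side-chain cleavage enzyme gene, had 8 reads in MEFs and 4 in CiSCs.

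Retinoic acid response genes rose, with 6 of 9 higher (median log2 fold change 2.38, camera adjusted p = 1.31e-04, adjusted p = 0.435 with an estimated correlation). The retinoic acid receptor gene Rarb went from 0.180 ± 0.112 to 104 ± 0.234 CPM. Lrat, which encodes the retinol-esterifying enzyme, was among the 8 largest increases, with 0 reads in MEFs and 14.8 ± 0.196 CPM in CiSCs (at least 193-fold higher). Of 32 tested HOX genes, which encode the transcription factors of axial identity, 24 rose and 3 fell (camera adjusted p = 4.31e-06, adjusted p = 0.435 with an estimated correlation). Hoxa5 rose from 3.59 ± 0.577 to 147 ± 5.27 CPM, Hoxa3 from 3.05 ± 0.123 to 88.7 ± 1.43 CPM and Hoxa4 from 2.03 ± 0.148 to 69.8 ± 10.3 CPM. In the list of fetal growth and imprinted genes, 7 of 11 rose, or 8 when adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.499 with an estimated correlation). The imprinted gene Mest rose from 13.3 ± 2.43 to 171 ± 9.39 CPM and Dlk1, a Notch-related ligand, from 42.1 ± 0.712 to 186 ± 6.78 CPM. The 4 Y-linked genes tested also rose (camera adjusted p = 0.0135, adjusted p = 0.555 with an estimated correlation). Ddx3y, for example, stood at 11.8 ± 0.498 CPM in MEFs and 39.3 ± 5.17 CPM in CiSCs. The other 7 of the largest increases lay outside the lists. Col6a5, a collagen VI chain gene, had 0 reads in MEFs and 28.0 ± 1.98 CPM in CiSCs (at least 364-fold higher), and the milk protein gene Csn3 had 1 read in MEFs and 135 ± 33.6 CPM in CiSCs. Fmo6, Slitrk1, Ccnb3 and Izumo1r had 0 reads in MEFs and means of 24.8, 18.5, 18.3 and 17.6 CPM in CiSCs, and Gpr83 had 1 read in MEFs and 60.1 CPM in CiSCs.

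All 18 tested macrophage and leukocyte markers fell (median log2 fold change -8.81, camera adjusted p = 3.60e-13, adjusted p = 0.499 with an estimated correlation). In MEFs these markers were abundant. The mannose receptor gene Mrc1 went from 311 ± 11.1 to 0.730 ± 0.357 CPM, the lysosomal gene Laptm5 from 791 ± 138 to 1.88 ± 0.709 CPM and the endotoxin co-receptor gene Cd14 from 749 ± 226 to 4.46 ± 0.229 CPM. Among the 8 largest single decreases, the cytokine gene Tnf, at 88.9 ± 9.34 CPM in MEFs, had 0 reads in CiSCs (at least 1254-fold lower), and so did Nlrp3, which encodes an inflammasome sensor (47.4 ± 6.70 CPM in MEFs), and Ms4a6b, Pira2, Gpr65 and Fgr. Acod1, the itaconate-producing enzyme of activated macrophages, and Ncf4, a subunit of the phagocyte oxidase, had 1 read each in CiSCs against means of 124 and 87.4 CPM in MEFs. Ms4a6b and Pira2 belong to families of near-identical genes, so their single values are uncertain. Alongside, 16 of 20 inflammatory cytokines and NF-kB targets fell (camera adjusted p = 1.10e-07, adjusted p = 0.285 with an estimated correlation), and 1 rose when adjusted over the list alone, with the chemokine gene Ccl2 at 507 ± 17.8 CPM in MEFs and 29.0 ± 5.41 CPM in CiSCs. Of 20 interferon response genes, 10 fell, or 11 when adjusted over the list alone, and 1 rose (camera adjusted p = 0.00573, adjusted p = 0.585 with an estimated correlation).

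Proliferation genes fell by small amounts, with 18 of 32 lower (median log2 fold change -0.51, camera adjusted p = 4.10e-04, adjusted p = 0.556 with an estimated correlation). The replication clamp gene Pcna stood at 125 ± 31.1 and 46.3 ± 0.429 CPM, and the helicase subunit gene Mcm5 at 64.0 ± 5.80 and 29.0 ± 2.30 CPM. Of 19 glycolysis and hypoxia genes, 11 fell, or 12 when adjusted over the list alone, and 3 rose (camera adjusted p = 0.0288, adjusted p = 0.499 with an estimated correlation). The list did not pass without the first MEF library (adjusted p = 0.0798) or without the second CiSC library (0.0511). The lactate transporter gene Slc16a3 fell from 157 ± 19.95 to 13.9 ± 0.108 CPM, while the oxygen-sensing hydroxylase gene Egln3 rose from 7.31 ± 1.67 to 136 ± 14.0 CPM. Of 78 ribosomal protein genes, 7 fell, or 2 when adjusted over the list alone and 13 by DESeq2 (median log2 fold change -0.42, camera adjusted p = 0.00357, adjusted p = 0.793 with an estimated correlation). This list did not pass without the second MEF library (adjusted p = 0.239) or the second CiSC library (0.0629), and many of its genes have processed pseudogenes that can share their reads. Fibroblast markers moved both ways, 8 higher and 6 lower of 26, or 8 lower when adjusted over the list alone (camera adjusted p = 0.829). Col3a1 rose from 1009 ± 56.3 to 3824 ± 329.7 CPM, the proteoglycan gene Dcn from 295 ± 13.7 to 2375 ± 347 CPM and the activation marker Fap from 5.06 ± 1.35 to 232 ± 3.51 CPM. Thy1 fell from 777 ± 127 to 138 ± 9.66 CPM and S100a4, which leukocytes also express, from 600.1 ± 151 to 3.39 ± 1.09 CPM. Col1a1 (9505 ± 1524 and 12486 ± 276 CPM) and Pdgfra (528 ± 146 and 473 ± 37.2 CPM) did not pass, but without the second MEF library both did (adjusted p = 0.00702 and 0.0230, edgeR).

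**Figure D2:**
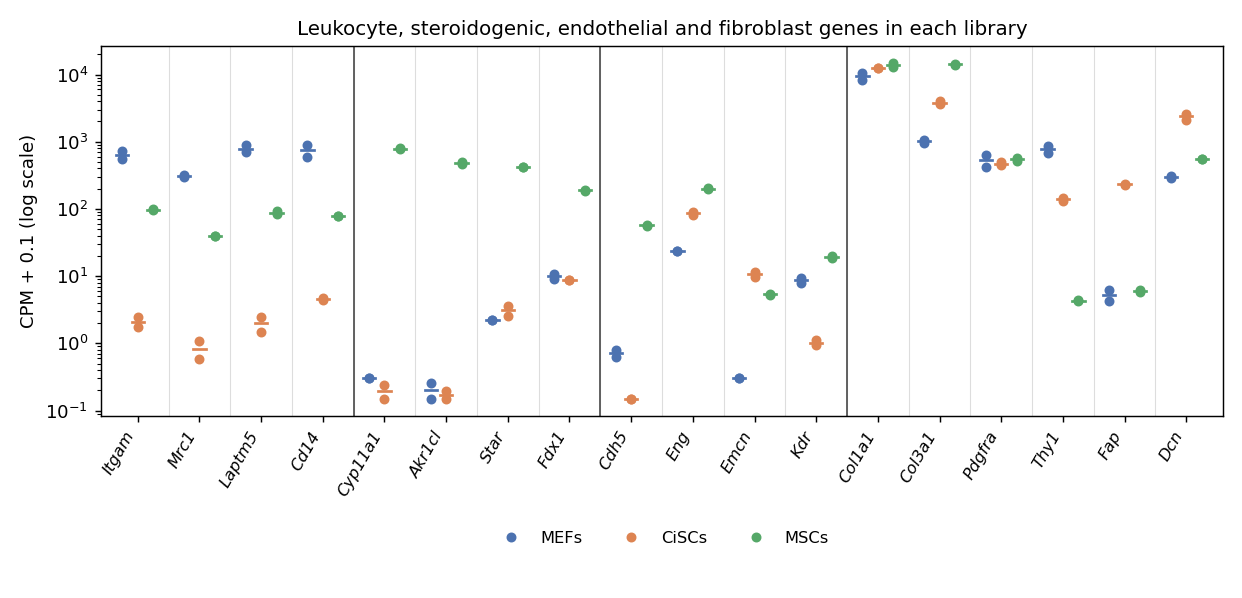
Levels of leukocyte, steroidogenic, endothelial and fibroblast genes (from left to right, separated by dark lines) in each library, as CPM + 0.1 on a log axis. Points are single libraries and bars the mean of 2. The 4 leukocyte genes were highest in MEFs and the 4 steroidogenic genes in MSCs, with Itgam at 637 CPM in MEFs and Cyp11a1 at 783 CPM in MSCs.

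In all, 6250 of 15272 genes differed between CiSCs and MEFs, 2998 higher and 3252 lower in CiSCs. At least 2-fold changes made up 1832 of the increases and 2174 of the decreases, and at least 16-fold changes 277 and 686. By camera, 10 of 36 tested gene lists differed, 4 up and 6 down, and 0 did with an estimated inter-gene correlation (3 at an unadjusted p under 0.05), while fry, which does not compare a list with other genes, called 25. The number of genes fell to 3470 without the first CiSC library and to 3395 without the second. It fell to 4713 and 4727 without the first or the second MSC library. It rose to 9487 without the first MEF library and to 7237 without the second. The MEF libraries were the least alike, with 1416 genes more than 2-fold apart against 477 in CiSCs and 415 in MSCs.

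MSCs were compared with MEFs to describe how the Sertoli cell libraries differed from the fibroblast libraries. The 2 groups also differed in age (postnatal day 60 against 13.5 days post coitum) and tissue, and both held markers of other cells. A difference can therefore not be assigned to cell type alone. Of 30 Sertoli cell markers, 26 were higher, and 1 was lower when adjusted over the list alone (median log2 fold change 5.85, camera adjusted p = 2.18e-11, adjusted p = 0.209 with an estimated correlation). Gata4 (Entrez Gene 14463) rose from 0.154 ± 0.00296 to 252 ± 17.7 CPM, a log2 fold change of 10.62 ± 0.22 (adjusted p = 8.56e-06, edgeR). Wt1 stood at 199.8 ± 34.8 CPM, Cldn11 at 318 ± 77.4 CPM and Clu at 6188 ± 1893 CPM in MSCs. Sox9 rose from 13.8 ± 2.51 to 78.7 ± 14.0 CPM, Inhbb from 77.4 ± 4.43 to 299 ± 13.7 CPM and Gdnf from 1.33 ± 0.119 to 19.4 ± 5.20 CPM. Aard had 1 read in MEFs and 108 ± 14.2 CPM in MSCs. Dmrt1, at 0 reads in MEFs, reached 11.2 ± 2.49 CPM. Amh, whose expression falls at puberty, was at 5.43 ± 0.235 CPM, and Fshr, with 8 reads in MSCs, had too few to be tested. Junction genes rose in 11 of 19 cases and fell in 2 (camera adjusted p = 0.00133, adjusted p = 0.376 with an estimated correlation), among them Cgn, which encodes cingulin, from 0.255 ± 0.140 to 209 ± 54.7 CPM. Steroidogenic, endothelial and myoid markers were higher in the same libraries.

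All 10 tested Leydig cell and steroidogenic genes rose in MSCs (median log2 fold change 8.86, or 7.11 with genes at 0 in a group set to their bound, camera adjusted p = 1.21e-08, adjusted p = 0.172 with an estimated correlation). The list held 13 genes. A listed gene near 0 in MEFs and CiSCs could be tested only with enough counts in MSCs, so the filter itself favours this result. Cyp17a1, Hsd17b3 and Lhcgr, also on the list, had 1, 0 and 3 reads in MSCs. Cyp11a1 stood at 783 ± 14.5 CPM, Akr1cl at 478 ± 24.4 CPM, the cholesterol carrier gene Star at 424 ± 1.86 CPM and Fdx1, the electron donor of Cyp11a1, at 189.5 ± 5.09 CPM. Hsd3b1, which makes progesterone and shares sequence with other genes of its family, was at 0 reads in MEFs and 106 ± 3.82 CPM in MSCs. Endothelial markers rose in 9 of 11 cases and fell in 2 (camera adjusted p = 0.00218, adjusted p = 0.269 with an estimated correlation), with the cadherin gene Cdh5 going from 0.614 ± 0.133 to 56.9 ± 1.40 CPM. Of 12 peritubular myoid and smooth muscle markers, 6 rose (camera adjusted p = 0.0464, adjusted p = 0.476 with an estimated correlation), including the kinase gene Mylk, from 27.5 ± 0.738 to 865 ± 58.7 CPM, but the list did not pass without the second MEF library (adjusted p = 0.188), without the first MSC library (0.0573) or without leukocyte-like genes (0.0596). Of 9 tested germ cell markers, 6 rose and 1 fell (camera adjusted p = 0.0483, adjusted p = 0.333 with an estimated correlation). The germ cell helicase gene Ddx4 was at 4.77 ± 1.22 CPM, and the GDNF receptor gene Gfra1 fell from 121 ± 8.79 to 0.321 ± 0.147 CPM. This list did not pass without the second MEF library (adjusted p = 0.0586), without the second MSC library (0.109), with a stricter filter (0.449) or with genes above 0 in all libraries (0.448). Leukocyte markers were lower than in MEFs in all 18 cases (median log2 fold change -3.28, camera adjusted p = 1.21e-08, adjusted p = 0.338 with an estimated correlation) but were still present, with Itgam at 97.4 ± 1.18 CPM and Laptm5 at 87.9 ± 5.42 CPM.

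Of 19 glycolysis and hypoxia genes, 17 rose in MSCs, or 18 when adjusted over the list alone (median log2 fold change 1.36, camera adjusted p = 2.00e-07, adjusted p = 0.172 with an estimated correlation), such as Bnip3, a mitophagy receptor gene induced by hypoxia, from 38.8 ± 0.123 to 349 ± 12.3 CPM. Sterol synthesis genes rose in 13 of 21 cases (camera adjusted p = 0.00130, adjusted p = 0.333 with an estimated correlation), with Hmgcs1 at 47.4 ± 16.2 and 227 ± 24.6 CPM. Retinoic acid response genes rose in 8 of 9 cases (camera adjusted p = 3.47e-04, adjusted p = 0.269 with an estimated correlation), interferon response genes in 12 of 20, or 13 when adjusted over the list alone, with 1 lower (camera adjusted p = 0.00352, adjusted p = 0.377 with an estimated correlation), and BMP response genes in 9 of 11 with 2 lower (camera adjusted p = 0.00397, adjusted p = 0.294 with an estimated correlation). Oasl2, an interferon-induced gene, rose from 34.4 ± 13.0 to 1767 ± 374 CPM. The Y-linked genes rose in 4 of 4 cases (camera adjusted p = 0.00444, adjusted p = 0.333 with an estimated correlation), with Ddx3y at 70.0 ± 12.1 CPM in MSCs.

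HOX genes were lower in MSCs in 21 of 32 cases, or 22 when adjusted over the list alone, and higher in 7 (camera adjusted p = 7.39e-04, adjusted p = 0.294 with an estimated correlation). The posterior genes Hoxd9 (4.92 ± 0.457 to 53.3 ± 0.443 CPM) and Hoxd10 (0.282 ± 0.0417 to 32.7 ± 2.05 CPM) were among those that rose. Fetal growth and imprinted genes fell in 8 of 11 cases and rose in 2 (camera adjusted p = 0.00450, adjusted p = 0.333 with an estimated correlation), with Dlk1 at 0.911 ± 0.290 CPM and Peg10 going the other way, from 12.6 ± 0.917 to 274 ± 31.0 CPM. Proliferation genes fell in 21 of 32 cases, or 22 when adjusted over the list alone (camera adjusted p = 2.08e-05, adjusted p = 0.333 with an estimated correlation) and ribosomal protein genes in 19 of 78, or 10 when adjusted over the list alone and 47 by DESeq2, with 1 higher, or 0 when adjusted over the list alone (camera adjusted p = 1.91e-06, adjusted p = 0.530 with an estimated correlation). Inflammatory cytokine and NF-kB target genes fell in 12 of 20 cases and rose in 3 (camera adjusted p = 0.00438, adjusted p = 0.269 with an estimated correlation), and p53 target and senescence genes fell in 6 of 16 (camera adjusted p = 0.0464, adjusted p = 0.377 with an estimated correlation). The inflammatory list did not pass when leukocyte-like genes were left out (adjusted p = 0.388). These include members of the list taken out for being lower in both groups, such as Tnf (88.9 CPM in MEFs and 1.82 CPM in MSCs). This loss therefore follows in part from the choice and does not show that leukocytes explain the fall. The p53 list did not pass without the first MEF library (0.168) or the first MSC library (0.0582). Fibroblast markers again moved both ways, 7 higher, or 8 when adjusted over the list alone, and 11 lower of 26 (camera adjusted p = 0.193). Thy1 fell to 4.22 ± 0.102 CPM and the matrix protein gene Postn from 4755 ± 230.1 to 115 ± 7.83 CPM, while Col3a1 rose to 14218 ± 188 CPM.

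Among the largest single increases in MSCs were those of C4b, a complement component gene with a near-identical neighbour, at 397 ± 21.1 CPM, and Mrap, an accessory protein of the melanocortin receptor for adrenocorticotropin, at 169.8 ± 14.5 CPM, both with 0 reads in MEFs. Slc30a2, Map3k21 and Ephb1 also had 0 reads in MEFs and reached 60.5, 46.3 and 31.6 CPM, and Tcf21, a transcription factor gene of mesenchymal cells, had 1 read in MEFs and 202 CPM in MSCs. The largest decreases were of Agtr2, the type 2 angiotensin receptor gene, which had 0 reads in MSCs and 58.1 ± 24.6 CPM in MEFs, of Dkk2, a Wnt antagonist gene, with 1 read in MSCs and 239 ± 51.6 CPM in MEFs, and of Crabp1, a retinoic acid-binding protein gene, which fell from 994 ± 191 to 0.296 ± 0.118 CPM. Chodl, Cpa6, Alkal1, Mab21l2 and Slc5a7 had 0 reads in MSCs and between 12.5 and 26.5 CPM in MEFs, of which Slc5a7 did not pass without the first or the second MSC library (adjusted p = 0.0538 and 0.0520, edgeR). Altogether 6497 genes differed, 3436 higher and 3061 lower in MSCs, of which 2510 and 1745 changed at least 2-fold. By camera 19 lists differed, 12 up and 7 down, and 0 with an estimated correlation (6 at an unadjusted p under 0.05), while fry called 33. The count of genes fell to 3551 and 3516 without the first or the second MSC library. It fell to 5197 and 5194 without the first or the second CiSC library. It rose to 9745 and 7551 without the first or the second MEF library.

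**Figure D3:**
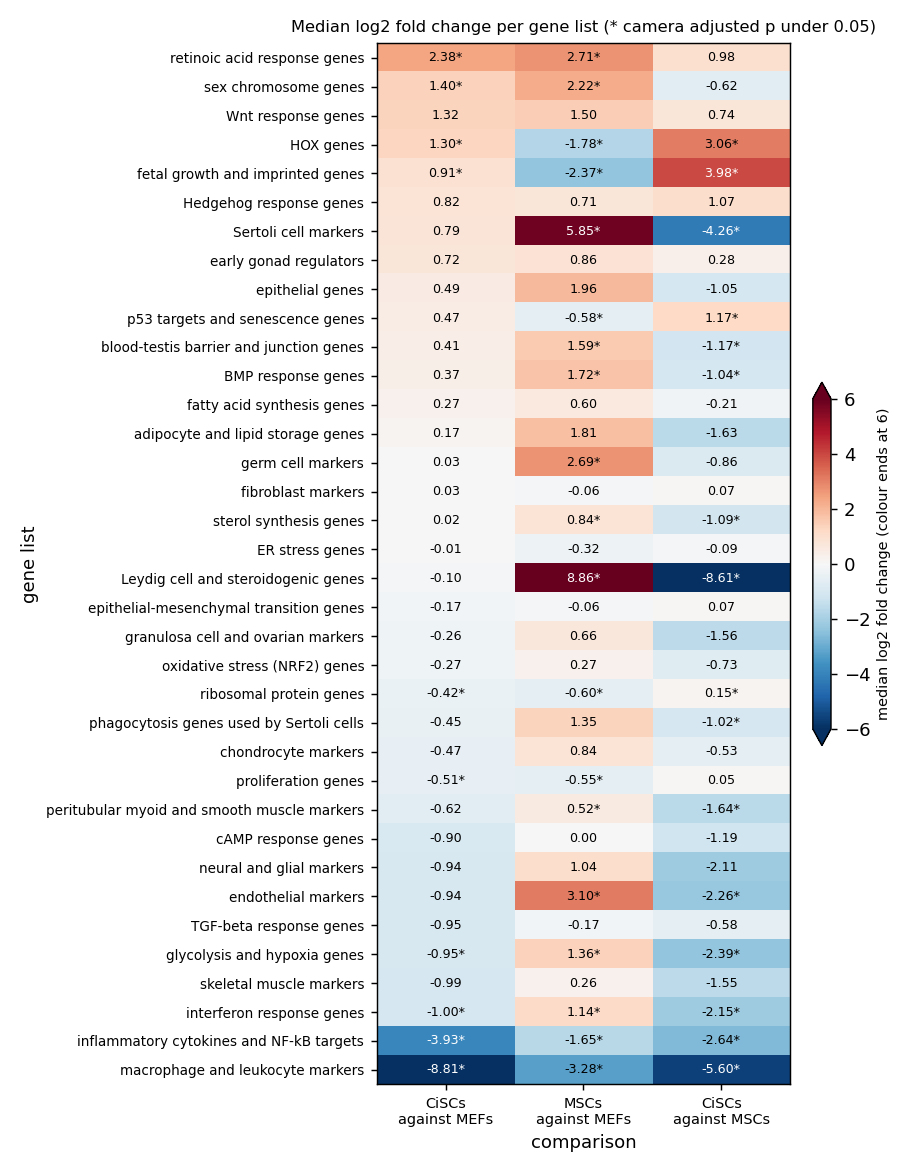
Median log2 fold change of the members of each of 36 gene lists (rows) in the 3 comparisons (columns). An asterisk marks a camera adjusted p under 0.05 at the preset inter-gene correlation, and 0 lists passed in each comparison with an estimated correlation (3, 6 and 7 at an unadjusted p under 0.05). The Sertoli cell marker list had medians of 0.79 for CiSCs against MEFs and 5.85 for MSCs against MEFs.

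CiSCs were then compared directly with MSCs, the comparison nearest to the stated purpose. Most Sertoli cell markers were lower in CiSCs than in MSCs, while Clu did not differ detectably and the retinoic acid-degrading enzyme gene Cyp26b1 was higher. Clu stood at 4375 ± 504 CPM in CiSCs and 6188 ± 1893 CPM in MSCs (log2 fold change -0.50 ± 0.23, adjusted p = 0.133, edgeR), and Krt18 at 12.8 ± 3.68 and 8.25 ± 0.0115 CPM (log2 fold change 0.64 ± 0.25, adjusted p = 0.0810, edgeR). Krt18 did pass without the first MEF library (adjusted p = 0.0299, edgeR), without the second (0.0320) and with only CiSCs and MSCs in the fit (0.0236). Of the 30 markers, 26 were lower and 2 higher, or 3 higher when adjusted over the list alone (median log2 fold change -4.26, camera adjusted p = 6.42e-09, adjusted p = 0.179 with an estimated correlation). Gata4 differed by a log2 fold change of -11.29 ± 0.23, Cldn11 by -8.19 ± 0.28, Wt1 by -3.20 ± 0.17, Sox9 by -2.32 ± 0.20 and Inhbb by -2.13 ± 0.15. Cyp26b1 was higher in CiSCs by 6.25 ± 0.20. Junction genes were lower in 11 of 19 cases and higher in 4 (camera adjusted p = 0.0387, adjusted p = 0.525 with an estimated correlation), and phagocytosis genes used by Sertoli cells in 7 of 11 with 1 higher (camera adjusted p = 0.0376, adjusted p = 0.367 with an estimated correlation). With only CiSCs and MSCs in the fit, neither list passed (adjusted p = 0.0617 and 0.0617), and the junction list did not pass with a stricter filter (0.0526) or with genes above 0 in all libraries (0.0587). The phagocytosis list did not pass without the first or the second MEF library (adjusted p = 0.0616 and 0.0608) or without leukocyte-like genes (0.0722). The scavenger receptor gene Cd36 stood at 0.379 ± 0.139 CPM in CiSCs and 76.9 ± 8.25 CPM in MSCs.

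Markers of several other cells were also lower in CiSCs than in MSCs, while germ cell markers did not pass as a list (5 of 9 lower and 2 higher, camera adjusted p = 0.351). Lower were 10 of 10 tested steroidogenic genes, from a list of 13 (median log2 fold change -8.61, or -7.12 with genes at 0 in a group set to their bound, camera adjusted p = 3.59e-08, adjusted p = 0.179 with an estimated correlation). So were 8 of 11 endothelial markers with 2 higher (camera adjusted p = 0.00599, adjusted p = 0.241 with an estimated correlation). Also lower were 9 of 12 myoid markers with 1 higher, or 2 when adjusted over the list alone (camera adjusted p = 0.00618, adjusted p = 0.513 with an estimated correlation) and 18 of 18 leukocyte markers (camera adjusted p = 6.42e-09, adjusted p = 0.367 with an estimated correlation). Nr5a1, the steroidogenic regulator SF-1, which Sertoli cells also express, had 0 reads in CiSCs and 143 ± 9.36 CPM in MSCs (at least 2024-fold lower). The cartilage proteoglycan gene Acan (233 ± 24.4 CPM in MSCs), Tcf21, Hsd11b1 (64.1 ± 3.07 CPM), the Leydig cell hormone gene Insl3 (62.4 ± 3.04 CPM), Slc30a2 and Ly6k (50.3 ± 3.31 CPM) had 0 reads in CiSCs as well.

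Glycolysis and hypoxia genes were lower in CiSCs in 18 of 19 cases and higher in 1 (median log2 fold change -2.39, camera adjusted p = 1.12e-07, adjusted p = 0.179 with an estimated correlation). Interferon response genes were lower in 16 of 20, or 18 when adjusted over the list alone (camera adjusted p = 2.80e-06, adjusted p = 0.367 with an estimated correlation). So were inflammatory genes in 14 of 20 with 1 higher (camera adjusted p = 1.52e-04, adjusted p = 0.179 with an estimated correlation). Sterol synthesis genes were lower in 14 of 21 (camera adjusted p = 0.00293, adjusted p = 0.367 with an estimated correlation) and BMP response genes in 8 of 11 with 1 higher (camera adjusted p = 0.0268, adjusted p = 0.367 with an estimated correlation). Slc16a3 stood at 13.9 ± 0.108 CPM in CiSCs and 405 ± 38.4 CPM in MSCs. HOX genes were higher in CiSCs in 24 of 32 cases, or 26 when adjusted over the list alone, and lower in 3 (median log2 fold change 3.06, camera adjusted p = 1.16e-08, adjusted p = 0.179 with an estimated correlation). Fetal growth and imprinted genes were higher in 10 of 11 with 1 lower (median log2 fold change 3.98, camera adjusted p = 7.50e-06, adjusted p = 0.241 with an estimated correlation). Igf2 stood at 1740.5 ± 134 CPM in CiSCs and 15.6 ± 1.59 CPM in MSCs. Of 16 p53 target and senescence genes, 10 were higher and 1 lower (camera adjusted p = 0.00203, adjusted p = 0.367 with an estimated correlation), among them Cdkn2a, which encodes cell-cycle inhibitors (46.2 ± 5.25 and 2.64 ± 0.952 CPM). Ribosomal protein genes were higher as a list, with 5 of 78 higher, or 2 when adjusted over the list alone (camera adjusted p = 0.0387, adjusted p = 0.745 with an estimated correlation). They did not pass as a list without the first CiSC library (adjusted p = 0.150), without the first MSC library (0.0687), with a stricter filter (0.0556) or without leukocyte-like genes (0.0780). Of 26 fibroblast markers, 11 were higher and 6 lower in CiSCs, or 7 lower when adjusted over the list alone (camera adjusted p = 0.112). Thy1 was higher by a log2 fold change of 5.04 ± 0.19 and Lum, a collagen-binding proteoglycan gene, stood at 250.0 ± 16.01 CPM against 4.91 ± 1.10 CPM. Among the largest increases, Agtr2 was at 158 ± 4.06 CPM in CiSCs and 0 reads in MSCs, Gdf10 at 149.7 ± 13.7 CPM with 2 reads in MSCs, Sim2 at 72.5 ± 0.0661 CPM with 1 read in MSCs, Mcpt8 at 82.2 ± 19.5 CPM with 1 read in MSCs and Sult1e1 at 10.7 ± 0.119 CPM with 0 reads in MSCs.

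In this comparison 6534 genes differed, 2697 higher and 3837 lower in CiSCs, of which 1543 and 2963 differed at least 2-fold. Fits to only the 2 groups compared gave 9328 genes here, 4845 for CiSCs against MEFs and 5220 for MSCs against MEFs. The near-equal counts of the main fit thus depend on fitting all 6 libraries together. By camera 16 lists differed, 4 up and 12 down, and 0 with an estimated correlation (7 at an unadjusted p under 0.05), while fry called 31. Leaving out 1 library moved the count of genes to 4037 (first CiSC library), 4205 (second CiSC library), 4017 (first MSC library), 3910 (second MSC library), 9356 (first MEF library) or 9369 (second MEF library).

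The last comparison asked how far the change from MEFs to CiSCs followed the change from MEFs to MSCs. Across the 15272 tested genes, the slope of the CiSC change on the MSC change, through the origin on the log2 scale, was 0.429 (r = 0.446 across genes, which are not independent replicates). The genes were also divided by the direction of the MSC change, after the slope had been seen. For the 2510 genes at least 2-fold higher in MSCs than in MEFs it was 0.200, and for the 1745 at least 2-fold lower it was 0.891. Without any 1 library and with a separate control for each change, these slopes ranged from 0.178 to 0.229 and from 0.850 to 0.932. The second set held leukocyte genes such as Itgam and Mrc1, which were lower in both groups than in MEFs and lower in CiSCs than in MSCs. Leukocyte-like genes were taken as all 18 leukocyte markers and the genes at least 16-fold lower in CiSCs and at least 2-fold lower in MSCs. Without these 497 genes the slope of the second set was 0.279. Over all other tested genes the slope without them was 0.253. The choice of these genes itself lowers both values. It does not require CiSCs to lie below MSCs, and it also took out Lgr5 and Gfra1, which were lowest in MSCs. The set is therefore not made of leukocyte genes alone. Of the 6497 genes that differed between MSCs and MEFs, 2993 (46.1%) also differed between CiSCs and MEFs in the same direction, 1321 of them higher in both and 1672 lower in both. Another 735 differed in opposite directions, and 2769 did not pass in CiSCs. Independent lists of these sizes would share 675 increases and 652 decreases and oppose in 1333 genes. The number changed in the same direction moved to 5987 and 3453 without the first or the second MEF library, 1796 and 1753 without the first or the second CiSC library, and 1658 and 1645 without the first or the second MSC library.

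Both changes were measured against the same MEF libraries, which adds agreement with no effect at all. The covariance of the changes was 1.32 against 0.0618 in 100 simulations with unchanged groups, a difference of 1.26, while the correlation simulated without effects was itself 0.501. With a different single MEF library as the control of each change, the slope was 0.367 with the first MEF library as the control of the CiSCs and 0.380 with the second, and the covariances were 1.26 and 1.15. Each of these controls was a single library, and part of the excess over independent lists may still come from the shared controls.

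**Figure D4:**
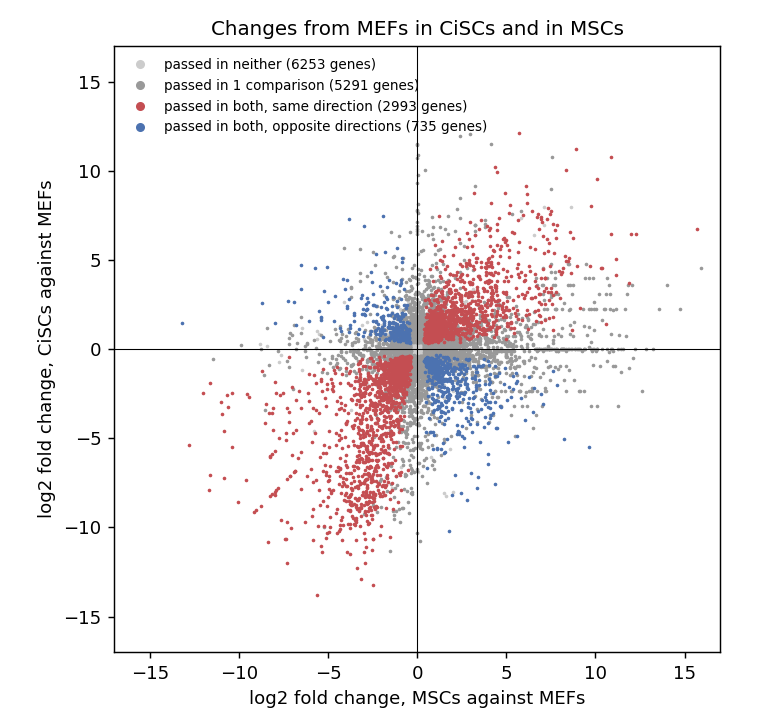
Log2 fold change of each of 15272 tested genes in CiSCs against MEFs (vertical axis) and MSCs against MEFs (horizontal axis). Red points are the 2993 genes that passed in both comparisons in the same direction, blue points the 735 that passed in opposite directions, and grey points the rest.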

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

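Of the tests in this part, the scaling, whole Leydig profile and male share tests were chosen after their results had been seen, and the second myeloid list and the X-linked partner test before. Changes against MEFs that differed between CiSCs and MSCs by the direct edgeR test of CiSCs against MSCs were singled out where they also went in opposite directions. In all, 407 genes changed at least 2-fold in opposite directions, 138 higher in CiSCs and lower in MSCs and 269 the reverse. Lists called in opposite directions against MEFs differed between CiSCs and MSCs by a median log2 fold change of 3.98 for fetal growth and imprinted genes, 3.06 for HOX genes, -2.39 for glycolysis and hypoxia genes and -2.15 for interferon response genes. With an estimated inter-gene correlation all of these calls against MEFs were lost (adjusted p from 0.435 to 0.585 in CiSCs and from 0.172 to 0.377 in MSCs). The glycolysis call in CiSCs was also lost without the first MEF library (0.0798) or the second CiSC library (0.0511). Among the named genes, the log2 fold change of CiSCs against MSCs was 14.61 for Agtr2, 11.28 for Gdf10, 11.28 for Mcpt8, 11.09 for Sim2, 7.66 for Dlk1, 7.65 for Hoxa5, 6.80 for Igf2, 5.67 for Lum and 4.86 for Mest, all higher in CiSCs. It was -15.17 for Acan, -13.31 for Hsd11b1, -10.05 for Cdh5, -7.65 for Cd36, -7.55 for Wnt4, -6.48 for Ddx4, -5.45 for Lpl and -4.86 for Slc16a3, all higher in MSCs. Fitted fold changes of genes with 0 reads in a group (Agtr2 in MSCs, Acan and Hsd11b1 in CiSCs) depend on the prior count and are not exact differences. The sizes are also uncertain for genes with few reads in a group, such as Gdf10, Mcpt8 and Sim2 in MSCs and Ddx4 in CiSCs. The opposite direction against MEFs was lost, on the side of the threshold, for Agtr2 and Ddx4 in CiSCs without the first CiSC library (adjusted p = 0.0754 and 0.0895, edgeR) or the second (0.0714 and 0.0930). For Sim2 in MSCs it was lost without the second MEF library (0.159), the first or second CiSC library (0.0729 and 0.0724) and the first or second MSC library (0.203 and 0.112), with the replicate number as a block (0.0522), with no filter (0.0563) and in the test against a fold of 1.5 (0.0735). For Ddx4 in CiSCs it was also lost with DESeq2 (adjusted p = 0.0575), and none of these 3 calls passed an adjusted p under 0.01.

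Leukocyte genes were lower in CiSCs than in MEFs, and one explanation is leukocytes in the MEF cultures that were fewer in the CiSC cultures. On a second list of 20 myeloid genes, 0 of which were on the first, 19 were at 10 CPM or more in both MEF libraries and at least 4-fold lower in CiSCs, as such cells would give, with Mpeg1 at 1243 and 1393 CPM in the MEF libraries and 2.15 and 3.79 CPM in the CiSC libraries. Scaling of the libraries is argued against, since the median log2 fold change of the first list was -8.68 or lower with each of 3 scalings. Repression of these genes by the compounds within the same cells stays open as an untested biological explanation. It was not determined how many of the falling genes would come from leukocytes, and the labels describe no sorting of the cells. Effects of passaging cannot be told apart from those of the compounds. Of the second list, 17 genes were also at 10 CPM or more in both MSC libraries.

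Steroidogenic genes were high in MSCs. Leydig cells that kept their whole profile are argued against, because Cyp17a1, Hsd17b3 and Lhcgr had 1, 0 and 3 reads against 29146 for Cyp11a1, at most 0.0137% of its level. Insl3, a Leydig cell hormone gene, points the other way, at 62.4 ± 3.04 CPM in MSCs. Scaling is argued against as well, with a median log2 fold change of the list, MSCs against MEFs, of 8.74 or higher with each of 3 scalings. Leydig cells that had lost part of their profile in culture, other steroidogenic cells, and expression by the Sertoli cells themselves stay open and were not tested.

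Y-linked genes were higher in CiSCs than in MEFs. A larger share of male cells would raise all 4 by the same factor if expression per male cell were equal in both groups. Their log2 fold changes were 1.74 for Ddx3y, 1.02 for Eif2s3y, 2.16 for Kdm5d and 1.07 for Uty. These differed by more than their standard errors (heterogeneity chi-square 24.1 on 3 degrees of freedom, p = 2.39e-05 by edgeR estimates). That p takes standard errors from 2 libraries per group as known and independent, which makes it too small. The mix of cells may also differ between the groups, so the test does not decide whether the male share is the only cause. Reads of the X-linked partners are argued against, because the median log2 fold change of the 4 partners was 0.21. A difference in the share of male cells, alone or combined with regulation of single genes, stays open, and the labels give no sex of the embryos.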

How the results depend on the processing

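The alternatives without rounding, without unmatched identifiers and without leukocyte-like genes were chosen after seeing the data, and the others before. Leaving out 1 library left a lone sample that is assumed to vary like the other groups. The number of changed genes then ranged from 3395 to 9487 for CiSCs against MEFs, from 3516 to 9745 for MSCs against MEFs and from 3910 to 9369 for CiSCs against MSCs. The genes changed in the same direction in CiSCs and MSCs ranged from 1645 (without the second MSC library) to 5987 (without the first MEF library), the slope from 0.399 to 0.4999 and the distance ratio from 1.01 to 1.11. No called gene changed its sign without any 1 library. With an adjusted p under 0.01 the counts were 3774, 4009 and 4324 in the order above, and with a test against a fold of 1.5 they were 3664, 3979 and 4282, with 1628 changed in the same direction, since both demand more of each gene. With an estimated inter-gene correlation, 0, 0 and 0 lists passed in the 3 comparisons. A higher correlation does not explain every loss, since some lists had an estimate below the preset 0.01. For inflammatory genes in CiSCs against MEFs it was -0.0365, yet the unadjusted camera p went from 6.11e-09 to 0.00792. For glycolysis and hypoxia genes in MSCs against MEFs it was -0.0269, and that p went from 2.23e-08 to 0.00894. Other lists had higher estimates, such as 0.638 for leukocyte markers. At this setting camera also refers each list to the 3 residual degrees of freedom of the fit, and at a preset correlation to many more. So few degrees of freedom raise a p-value by themselves. The loss of a call at this setting therefore cannot be assigned to correlation between genes. With the first MEF library as the control of CiSCs and the second as that of MSCs the slope was 0.367, without the shared control. Without leukocyte-like genes the distance ratio was 1.29 and the slope 0.253. That choice takes out genes for being lower in both groups, so it lowers the slope and raises the ratio by its own construction. It also takes out falling members of lists, such as Tnf and Lgr5, so list calls at this setting are not independent of it.

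With the replicate number as a block, 5468, 5672 and 5814 genes passed, of which 5407, 5621 and 5769 also passed without it. The deviations of libraries with the same number from their group means correlated across genes by -0.215 (MEFs and CiSCs), 0.138 (MEFs and MSCs) and -0.129 (CiSCs and MSCs), so the numbers were not taken to pair the samples. DESeq2 called 6269, 6515 and 6478 genes, of which 5843, 6078 and 6110 were also called by edgeR with the same sign. Over all alternatives, the called side of named genes held in 5118 cases, was lost in 73 and gained in 23, with 0 changes of direction. That of lists held in 1623 cases, was lost in 70, 45 of them with an estimated correlation, and gained in 29. Rescaling and other pseudocounts for normalised values did not apply to counts. With 2 libraries per group, the simulated test recovered 20.9% to 34.3% of 2-fold changes and at most 4.48% of 1.5-fold changes. It altered few genes, and in the data, where many more genes changed, changes under 2-fold were also called. Levels of a few reads were not distinguished from 0.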

Other observations

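Of the tests in this part, that of HOX genes by paralog number was chosen after the result had been seen, and that of the second cell-cycle lists before. Gene groups not described so far moved in part. Of 12 Wnt response genes, 7 rose in CiSCs against MEFs, or 9 when adjusted over the list alone, and 3 fell (camera adjusted p = 0.0858), and the list passed without leukocyte-like genes (adjusted p = 0.0203). That set holds the list member Lgr5, taken out for falling in both groups, so this pass is not independent of the choice. Lgr5, an R-spondin receptor gene, fell from 177 ± 45.5 CPM in MEFs to 0.449 ± 0.0396 CPM in CiSCs and 0.162 ± 0.154 CPM in MSCs, and Tcf7, a Wnt effector gene, rose from 0.307 ± 0.0666 to 6.24 ± 0.4201 and 6.52 ± 0.394 CPM. Of 14 cAMP response genes, 8 fell in CiSCs and 2 rose (camera adjusted p = 0.0661, edgeR for single genes), and the immediate early gene Nr4a1 went from 247 ± 3.01 to 30.0 ± 1.78 CPM. That list passed without the second MSC library (adjusted p = 0.0480), with no filter (0.0357) and with a stricter filter (0.0389), with genes above 0 in all libraries (0.0125) and without leukocyte-like genes (0.0297). Wnt4, an ovarian and stromal signal gene, was at 7.12 ± 2.35 CPM in MEFs, 0.378 ± 0.00522 CPM in CiSCs and 71.9 ± 2.84 CPM in MSCs. Lpl, which encodes lipoprotein lipase, was at 50.6 ± 7.18, 12.7 ± 0.560 and 552 ± 65.2 CPM in the same order, and the glutathione transferase gene Gstm1 at 49.1 ± 19.3, 42.8 ± 0.158 and 1039 ± 90.8 CPM.

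A hypothesis for the HOX genes is that their rise in CiSCs may be part of a response to retinoic acid, which acts first on genes of low paralog number. Across 32 HOX genes, which are not independent replicates, Spearman's rho between paralog number and the log2 fold change of CiSCs against MEFs was -0.373 (two-sided permutation p = 0.0361, adjusted p = 0.0722 over 2 comparisons). The median was 1.76 for the 14 genes with a paralog number up to 5 and 1.00 for the 18 others. For MSCs against MEFs rho was 0.129 (permutation p = 0.478). The adjusted p misses 0.05, so the test does not decide the hypothesis.

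A hypothesis for the lower proliferation genes in CiSCs is that a part of the cells may have stopped dividing, which would lower replication and mitosis genes alike. On second lists without members of the first, 14 replication genes had a median log2 fold change of -0.56, with 8 lower by edgeR, and 12 mitosis genes a median of -0.431, with 5 lower. The second median lies between the bounds set before the test, so the hypothesis is left undecided.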
